A study of Mus musculus with 10 samples.

How the data were processed

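Group 2 innate lymphoid cells (ILC2s) were sorted from mouse bone marrow and RNA was sequenced after 24 h of culture. Per the labels, marrow came from long bones, hips and spines, lineage-positive cells (CD3, CD19, Gr1, Ter119) were depleted with magnetic beads, and ILC2s were sorted as lineage-negative, cKit-negative cells positive for Sca1, CD25 and CD127. Cells were kept at 5000 per 100 µl with IL-2 at 50 U/ml and IL-7 at 50 ng/ml, with or without IL-33 at 10 ng/ml. The species of the recombinant IL-33 differs between the labels and is left open here. Libraries were made with the NEBNext Ultra RNA kit, which does not mark strand.

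The deposited values are raw read counts per Ensembl gene, and the authors did not normalise them, as the whole numbers and unequal column sums show. Per the submitters' processing notes, reads passed through fastp, STAR and featureCounts with the mouse build mm10. Tool versions, the annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Of 54532 genes in the table, 54495 were matched by identifier to GENCODE annotation of GRCm38 (the assembly of mm10) for symbols and positions, and 37 kept their identifier only. Where identifiers shared a symbol (111 symbols), the identifier with most counts kept it. No counts were found for 15889 genes.

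Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were removed with filterByExpr over the 3 groups, which left 14423 genes. Libraries were scaled by the trimmed mean of M values (TMM), and CPM means counts scaled in this way to a common total unless stated otherwise. A quasi-likelihood model (glmQLFit with robust estimation, glmQLFTest) was fitted to all 10 libraries with the group as the only term, so that all comparisons shared one estimate of the spread. Log2 fold changes are given with their standard error (SE), p-values are two-sided and adjusted by Benjamini-Hochberg over the genes tested, and 0.05 was the threshold. Group levels are means ± SD over libraries. Scaling by library size alone moved the median log2 fold change of all tested genes from -0.09 to -0.49 for IL-33, from 0.06 to 0.35 for ST2 loss, and from 0.17 to 0.88 for ST2-/- against WT with IL-33, so all changes are relative to the TMM reference.

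The 29 gene lists (pathways, ILC2 genes and markers of other cell types) and the rule for naming genes were fixed before the data were examined. The rule took the 8 genes with the largest rise and the 8 with the largest fall in each of 2 comparisons. They were taken from protein-coding genes past the threshold whose groups did not overlap. Their mean CPM over the 2 groups compared was at least 10. For counts and correlations over many genes, such a mean is over all 10 libraries. The rule added 12 genes regardless of result (Il1rl1, Il5, Il13, Il4, Il9, Il6, Csf2, Areg, Gata3, Il2ra, Il7r, Klrg1) and up to 4 members with the smallest adjusted p of each list described. Other genes named in the text were chosen after their values were seen, except the sex-linked transcripts, which were a fixed list. Lists with at least 3 tested members (27 of 29) were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, and adjusted over the lists. The same test with the correlation estimated from the data, and fry, were alternatives.

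Total counts per library ran from 8941691 to 21605937. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A gene with no count in a group was set against a floor of 3 counts over that group. Whether the replicates are separate animals or cultures is not given in the sources used here, so p-values measure the spread between these samples, which may be technical.

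The model was tested on data simulated from the means and library sizes of these samples. For the IL-33 comparison, with 13618 genes in the test, 51 of 96 genes changed 2-fold and 59 of 93 changed 4-fold were recovered, with 11 false calls (9.09% of calls). For ST2 loss, with 13600 genes in the test, 46 of 95 and 64 of 94 were recovered, with 7 false calls (5.98%). Both shares of false calls lay above the threshold of 0.05. Far fewer genes changed in these simulations than were called in the real comparisons, so the shares recovered do not measure recovery there. In each comparison the simulated list that changed was called and 0 of 20 unchanged lists were. Genes were drawn independently here, so these lists do not test camera under correlation between genes. For the real cell cycle list the estimated correlation was 0.76 in ST2 loss.

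Alternatives were median-of-ratios size factors, library size scaling, no filter, a stricter filter (CPM of at least 1 in at least 3 libraries and a mean CPM of at least 5), protein-coding genes alone, the replicate number as a block, only the 2 groups compared, the Wald test of DESeq2 1.42.0, limma-voom, and leaving out each library in turn. After the data were seen, 3 more were added: a term for Y-linked transcripts, leaving out library 3 of WT without IL-33 and of ST2-/-, and leaving out the 3 libraries with most olfactory receptor reads. Correlations of fold changes were set against 40 simulated draws of unchanged groups against the same controls, and overlaps of calls against 12 draws. No library was left out of the results given first.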

Results

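Transcripts were counted in bone marrow ILC2s, innate lymphocytes that make type 2 cytokines, after 24 h of culture. The alarmin IL-33 acts on these cells through its receptor ST2, encoded by Il1rl1. WT (BL/6) ILC2s without IL-33 gave 3 libraries, WT ILC2s with IL-33 at 10 ng/ml gave 4, and ST2-/- ILC2s without IL-33 gave 3. Total counts were 21067572, 21605937 and 14469386 in WT without IL-33, 18023363, 8941691, 15590027 and 15821921 in WT with IL-33, and 16866783, 11936197 and 12944350 in ST2-/- (libraries in order of their number). No pair of replicates held identical values, and each of the 12 pairs differed by more than sampling noise (chi-square per gene 16.1 to 52.3). Genes with at least 10 counts numbered 13193 to 13839 in WT without IL-33 and 10760 to 12268 with IL-33. They numbered 13474, 14467 and 18034 in ST2-/- libraries 1, 2 and 3. The first principal component (54.2% of the variance) set the 3 groups in the order ST2-/-, WT without IL-33, WT with IL-33. The second component (18.6%) set library 3 of WT without IL-33 and libraries 2 and 3 of ST2-/- apart from the other libraries without IL-33.

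Il1rl1 (ENSMUSG00000026069, mm10 chromosome 1, 40429570 to 40465415) was examined first because it checks the genotype labels. It stood at 241, 235 and 230 CPM in WT without IL-33 and at 105, 134 and 138 CPM in ST2-/-, which is 44.7%, 56.9% and 58.7% of the WT mean. The fall in ST2-/- had a log2 fold change of -0.90 (SE 0.14, adjusted p = 0.00221), and all 3 ST2-/- libraries lay below all 3 WT libraries. Counts summed over a whole gene still hold exons outside a deletion, so they check the labels only in part. With a term for Y-linked transcripts the log2 fold change was -0.81 (SE 0.21, adjusted p = 0.0901; 2.60e-07 to 0.0901 over the alternatives). Added IL-33 also lowered Il1rl1 in WT cells, to 106 ± 13.4 CPM from 235 ± 5.46 (log2 fold change -1.15, SE 0.13, adjusted p = 3.12e-05). Y-linked transcripts (Ddx3y, Uty, Kdm5d and Eif2s3y) summed to 182 CPM and 216 CPM in ST2-/- libraries 1 and 3 and to at most 0.16 CPM in the other 8 libraries. Xist was at 0.05 CPM and 0 CPM in those 2 libraries and at 29.3 to 46.6 CPM elsewhere. The labels used here give no sex.

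The response of WT ILC2s to IL-33 was led by secreted cytokines. Il9 (ENSMUSG00000021538, chromosome 13, 56479277 to 56482246) reached 24431 ± 7318 CPM (n = 4) from 4.69 ± 4.92 CPM (n = 3), a log2 fold change of 12.43 (SE 0.80, adjusted p = 7.78e-07 in edgeR). Il5 (ENSMUSG00000036117, chromosome 11, 53720794 to 53725106), the eosinophil growth factor, reached 28186 ± 5120 CPM from 229 ± 121 CPM, 123-fold higher. Csf2, which encodes GM-CSF, rose 60.4-fold to 5204 ± 1260 CPM, Il6 rose 60.9-fold to 544 ± 77.0 CPM, and Il13 rose 32.8-fold to 502 ± 160 CPM. Hamp, the iron hormone hepcidin, had no count in the 3 WT libraries without IL-33 and 81.3 ± 32.6 CPM with it, at least 1634-fold higher against a floor of 3 counts over the group. In total 2805 genes rose and 2382 fell (5187 of 14423, edgeR quasi-likelihood test), of which 1115 and 1156 changed at least 2-fold.

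Among other protein-coding genes with the largest rise at a mean CPM of at least 10, the interleukins Il10, Il22 and Il24 went to 73.2 ± 47.3, 732 ± 184 and 165 ± 69.3 CPM from 0.253 ± 0.16, 3.06 ± 3.37 and 0.831 ± 0.847 CPM. The growth factor receptor Egfr went to 61.8 ± 21.4 CPM from 0.066 ± 0.021, and the opioid precursor Penk to 43.1 ± 11.2 CPM from 0.368 ± 0.262. Areg, the epidermal growth factor family ligand amphiregulin, rose 8.33-fold and Il4 1.90-fold (adjusted p = 0.00195). The largest falls at this level, among genes whose groups did not overlap, were in Osbpl5 (29.0-fold lower, 0.912 ± 0.308 against 26.9 ± 11.9 CPM), the chemokine receptor Ccr9 (25.5-fold), St6galnac5 (22.5-fold), Ms4a6b (18.7-fold), Cd200r3 (17.6-fold), Serpinb1a (17.5-fold), Ms4a4b (14.0-fold) and Epcam (12.4-fold, 34.7 ± 8.85 against 434 ± 81.3 CPM). The rule required the groups of the genes with the largest rises and falls not to overlap. Areg and Il4, named regardless of result, also separated all 4 libraries with IL-33 from all 3 without. In all, 6632 genes did so (46.0% of those tested, 5.71% by chance for 4 against 3). Ms4a6b, Ms4a4b and Serpinb1a belong to families of similar genes whose reads the counting could share. Ccr9 overlaps Lztfl1 and St6galnac5 overlaps Pigk on the opposite strand, and the strand setting was not stated, so these values are uncertain. Library size scaling gave 1366 genes up and 4864 down, and without library 1 of WT without IL-33 the genes down numbered 1470.

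Of 12 ILC2 effector cytokine genes, 10 rose and 2 did not pass, and the counts were the same when adjusted over the list alone (median log2 fold change 5.48; camera adjusted p = 1.42e-20). NF-kB targets rose in 14 of 19 and fell in 1 (15 and 1 adjusted over the list alone, camera adjusted p = 2.44e-10). By smallest adjusted p the first were Nfkb2 (1.77), Nfkbia (2.77), Tnip1 (1.71) and Traf1 (2.99 on the log2 scale), and the largest rise in the list was 3.34. Nfkbia and Tnip1 encode inhibitors of NF-kB signalling, and the member that fell was Nfkb1 (-0.74). In the TNF and TNF receptor superfamily, 9 of 14 genes rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.000524). Log2 fold changes were 5.26 for Tnfrsf8, 4.92 for Tnfsf8, 3.00 for Tnf and 1.73 for Tnfrsf25, and Tnfsf11 and Ltb fell (-1.70 and -0.76). These 3 calls held with an estimated correlation.

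All 16 genes of the MYC and ribosome biogenesis list rose, also when adjusted over the list alone (median log2 fold change 1.08; camera adjusted p = 3.43e-14, adjusted p = 0.0937 with an estimated correlation). Npm1 (1.99), Nop58 (1.09), Ncl (1.38) and Wdr43 (1.02), which act in the nucleolus, had the smallest adjusted p. Of 17 glycolysis genes, 11 rose, among them Pgam1 (1.42), Tpi1 (1.14), Ldha (0.93) and Pgk1 (0.84), and Hk1 fell (-0.51), with the same counts adjusted over the list alone (camera adjusted p = 0.00216, adjusted p = 0.54 with an estimated correlation). Targets of p53 rose in 9 of 12, again when adjusted over the list alone (camera adjusted p = 1.39e-07, adjusted p = 0.0946 with an estimated correlation). Among them were the death receptor gene Tnfrsf10b (1.72), Mdm2 (1.65), which limits p53, Ccng1 (1.40) and Phlda3 (1.37). Haematopoietic growth factors rose in 6 of 11 and fell in 2, the same adjusted over the list alone (camera adjusted p = 0.00325, adjusted p = 0.137 with an estimated correlation). Csf2, Il5, Il6 and Il3 of this list are also effector cytokines, and Flt3l (-1.56) and Csf1 (-1.28) fell.

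Interferon response genes fell in 14 of 16 and Bst2 rose, also when adjusted over the list alone (median log2 fold change -1.75; camera adjusted p = 2.65e-08, adjusted p = 0.0946 with an estimated correlation). Irf7 (-3.27), Irf9 (-1.77), Rtp4 (-3.88) and Stat1 (-1.43) had the smallest adjusted p. ILC2 identity genes fell in 12 of 21 and rose in 3 (14 and 3 adjusted over the list alone; camera adjusted p = 0.00325, adjusted p = 0.137 with an estimated correlation). The IL-25 receptor gene Il17rb was 7.71-fold lower, and Thy1 (-1.96) and the TSLP receptor gene Crlf2 (-0.99) also fell. Il2ra (CD25, 2.62-fold higher), Gfi1 (1.08) and Klrg1 (1.32, adjusted p = 0.00845) rose, while Il7r (-0.80, adjusted p = 0.00139) and Gata3 (-0.63, adjusted p = 0.00937), the ILC2 transcription factor, fell. Single libraries with IL-33 lay apart from the other 3 for Tnfsf8 and Mdm2 (22.2 and 281 CPM in library 2), Serpinb1a (29.1 CPM in library 3) and Klrg1 (47.5 CPM in library 4). Gata3 did not pass without library 1 (adjusted p = 0.0798) or library 2 (0.0748) of WT without IL-33 (1.05e-05 to 0.0798 over the alternatives).

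**Figure D1:**
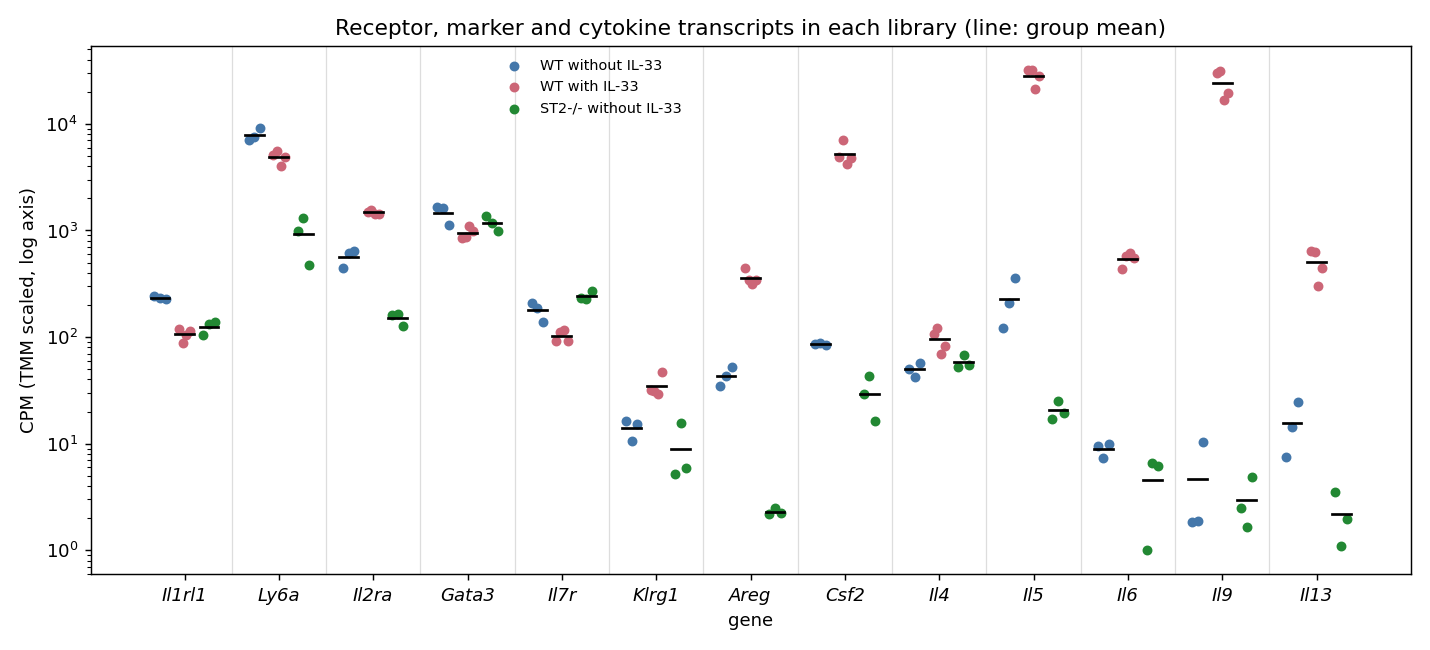
TMM-scaled CPM on a log axis for receptor, marker and cytokine transcripts, with a point per library and a line at each group's mean. Il5 lies at 28186 CPM on average in WT with IL-33, 229 CPM in WT without and 20.6 CPM in ST2-/-, and Il1rl1 at 106, 235 and 126 CPM.

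ILC2s labelled ST2-/- were compared with WT cells in the absence of added IL-33, which asks what the receptor contributes when no ligand is supplied. Areg (ENSMUSG00000029378, chromosome 5, 91139599 to 91148432) was 18.9-fold lower in ST2-/- at 2.30 ± 0.151 CPM against 43.4 ± 8.65 (n = 3 each; log2 fold change -4.24, SE 0.20, adjusted p = 3.57e-07 in edgeR). Il5 was 11.2-fold lower (20.6 ± 4.09 against 229 ± 121 CPM, adjusted p = 0.000218), Il13 6.68-fold lower (2.20 ± 1.25 against 15.5 ± 8.64 CPM, adjusted p = 0.00399) and Csf2 2.92-fold lower (29.5 ± 13.4 against 86.1 ± 1.54 CPM, adjusted p = 0.00486). Transcripts of 2 sort markers fell as well, Ly6a (Sca1) 8.59-fold to 919 ± 422 CPM and Il2ra (CD25) 3.75-fold to 151 ± 20.4 CPM. In total 728 genes rose and 1450 fell (2178 of 14423, edgeR quasi-likelihood test), with 4573 genes (31.7%) whose groups did not overlap against 10% by chance. At a mean CPM of at least 10 over all 10 libraries, 501 of 7738 genes rose and 1275 fell.

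Other protein-coding genes with the largest falls, at a mean CPM of at least 10 and with groups that did not overlap, were the granzyme gene Gzmb (35.2-fold, 2.27 ± 2.06 against 82.3 ± 37.9 CPM), Ly6c1 (14.4-fold), Prdm1, which encodes the repressor Blimp-1 (11.9-fold), Avil (9.41-fold) and the steroidogenic enzyme gene Cyp11a1 (8.81-fold, 102 ± 36.7 against 897 ± 199 CPM). Genes that rose most under the same limits included Slfn2 (6.74-fold, 846 ± 223 against 125 ± 17.6 CPM, adjusted p = 1.34e-05), the lymphotoxin gene Ltb (5.27-fold, 608 ± 119 against 115 ± 17.3 CPM), Cpne7 (10.6-fold), Tbc1d4 (7.18-fold), Frat2 (7.12-fold) and Tmem71 (5.24-fold). Cxcr4 (36.3 ± 54.3 against 1.70 ± 0.477 CPM, adjusted p = 0.0446) and Ctse (121 ± 156 against 12.8 ± 4.35 CPM, adjusted p = 0.0427) also passed, but ST2-/- library 3 held 99.0 and 301 CPM of them and the other ST2-/- libraries at most 6.72 and 33.3. Cxcr4 did not pass without that library (adjusted p = 0.0726; 0.00103 to 0.495 over the alternatives), and Cxcr4 failed in 15 of 22 and Ctse in 14 of 21 alternatives. Log2 fold changes that did not pass were 0.22 for Il4, -0.56 for Il9, -1.01 for Il6, -0.32 for Gata3, 0.44 for Il7r and -0.66 for Klrg1 (adjusted p 0.0957 to 0.572). Ly6a, Ly6c1 and Slfn2 have near relatives, and Avil overlaps Tsfm on the opposite strand, so their counts are uncertain.

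Unfolded protein response genes, mostly chaperones and factors of the endoplasmic reticulum, fell in 12 of 18 (13 adjusted over the list alone; median log2 fold change -0.73; camera adjusted p = 1.64e-11), a call that held with an estimated correlation. Manf (-1.38), Sdf2l1 (-1.50), Creld2 (-0.77) and Asns (-0.96) had the smallest adjusted p. Cell cycle genes fell in 14 of 25 (21 adjusted over the list alone; median -1.10; camera adjusted p = 2.49e-10, adjusted p = 0.44 with an estimated correlation), with Pcna at -1.21, Rrm2 at -1.83, Ccne1 at -1.99 and Tyms at -1.26. Glycolysis genes fell in 8 of 17 (12 adjusted over the list alone; camera adjusted p = 4.45e-08, adjusted p = 0.332 with an estimated correlation), among them Pgk1 (-1.31), Gapdh (-1.36), Ldha (-1.06) and Eno1 (-0.85). The effector cytokine list fell in 4 of 12, also when adjusted over the list alone (median -1.26, or -1.05 with Il3, which had no count in ST2-/-, at its bound; camera adjusted p = 5.63e-07, adjusted p = 0.135 with an estimated correlation). AP-1 and MAPK response genes fell in 8 of 19 (9 adjusted over the list alone; camera adjusted p = 0.00052, adjusted p = 0.332 with an estimated correlation), with Fosl1 at -2.43, Egr1 at -2.31, Ier3 at -1.27 and Batf at -1.01.

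The 4 other lists past the threshold also fell. Cholesterol biosynthesis genes fell in 6 of 18 (7 adjusted over the list alone; camera adjusted p = 0.00014, adjusted p = 0.474 with an estimated correlation), among them Msmo1 (-0.74), Cyp51 (-0.95), Nsdhl (-0.79) and Idi1 (-1.15). MYC and ribosome biogenesis genes fell in 6 of 16 (8 down and 1 up adjusted over the list alone; camera adjusted p = 0.000762, adjusted p = 0.474 with an estimated correlation), with Nop58 at -0.69, Ncl at -0.73, Fbl at -0.62 and Gnl3 at -0.42. The IL-2 and IL-7 STAT5 response fell in 6 of 17 (8 down and 1 up adjusted over the list alone; camera adjusted p = 0.002, adjusted p = 0.44 with an estimated correlation). Its members Socs3 (-2.77), Il2ra (-1.91), Pim2 (-1.06) and Ccnd3 (-0.99) fell, and its median of -0.23 became 0.07 with library size scaling. Haematopoietic growth factors fell in 3 of 11 (Il5, Csf2 and Osm) and Lif rose, also when adjusted over the list alone (camera adjusted p = 0.0218, adjusted p = 0.332 with an estimated correlation). Without the 3 libraries richest in olfactory receptor reads the cholesterol, MYC and STAT5 calls were lost (adjusted p = 0.179, 0.231 and 0.142), and the growth factor call was lost in 4 of 19 alternatives (adjusted p up to 0.388), among them those without ST2-/- library 1 or 3.

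These gene groups moved together with other differences between the libraries. Y-linked transcripts marked ST2-/- libraries 1 and 3 and no WT library, and with a term for them 38 genes were up and 44 down in ST2-/-. In that fit 13 of 19 named calls held, and Il13, Csf2, Avil, Cpne7, Cxcr4 and Ctse did not pass (adjusted p 0.0633 to 0.505). Avil went from -3.23 (SE 0.40) to -3.15 (SE 0.68) and Il13 from -2.74 (SE 0.48) to -3.79 (SE 0.84), so these calls ended with the wider SE. Csf2 went from -1.55 (SE 0.29) to about -1 (SE 0.34), Cpne7 from 3.40 (SE 0.48) to 2.32 (SE 0.49), Cxcr4 from 4.44 (SE 1.25) to 2.01 (SE 1.26) and Ctse from 3.23 (SE 0.89) to 1.38 (SE 0.88), where the fold change itself was smaller. No WT library held Y-linked transcripts, so the term takes up ST2-/- libraries 1 and 3. This fit therefore sets ST2-/- library 2 alone against WT, and its smaller fold changes do not show an effect of sex. Reads of olfactory and vomeronasal receptor genes, which are silent in most tissues, stood at 494 and 934 CPM (library size scaling) in ST2-/- libraries 2 and 3, 302 CPM in library 3 of WT without IL-33 and 41.5 to 122 CPM in the other 7. Without the 3 libraries richest in these reads, which leaves 1 ST2-/- library, Il13 (-1.65, SE 0.72, adjusted p = 0.232; 1.40e-05 to 0.232 over the alternatives) and Ltb (1.95, SE 0.52 against 2.40, SE 0.28; adjusted p = 0.0875; 3.69e-36 to 0.0875) did not pass. The log2 fold change of Ltb stayed between 1.95 and 2.69 over the alternatives. Marker sums of neutrophils and monocytes were 760 CPM in ST2-/- and 432 CPM in WT on average. Those of NK cells and ILC1 were 15.2 and 92.3 CPM, or 13.0 and 10.0 CPM without Gzmb, which WT ILC2s hold at 82.3 CPM. Mast cell and basophil markers summed to 0.78, 3.86 and 106 CPM in libraries 1, 2 and 3 of WT without IL-33. In ST2-/- libraries 1, 2 and 3 these sums were 8.74, 3.57 and 26.25 CPM. Genes up and down numbered 201 and 680 without library 2 of WT, 458 and 956 without library 3 of WT, and 458 and 817 without library 3 of ST2-/-. Library size scaling gave 2290 up and 601 down, the stricter filter 1112 up and 1211 down, and leaving out library 3 of both groups 240 up and 443 down, with Il13 at -2.15 (SE 0.56) no longer past the threshold (adjusted p = 0.0658).

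**Figure D2:**
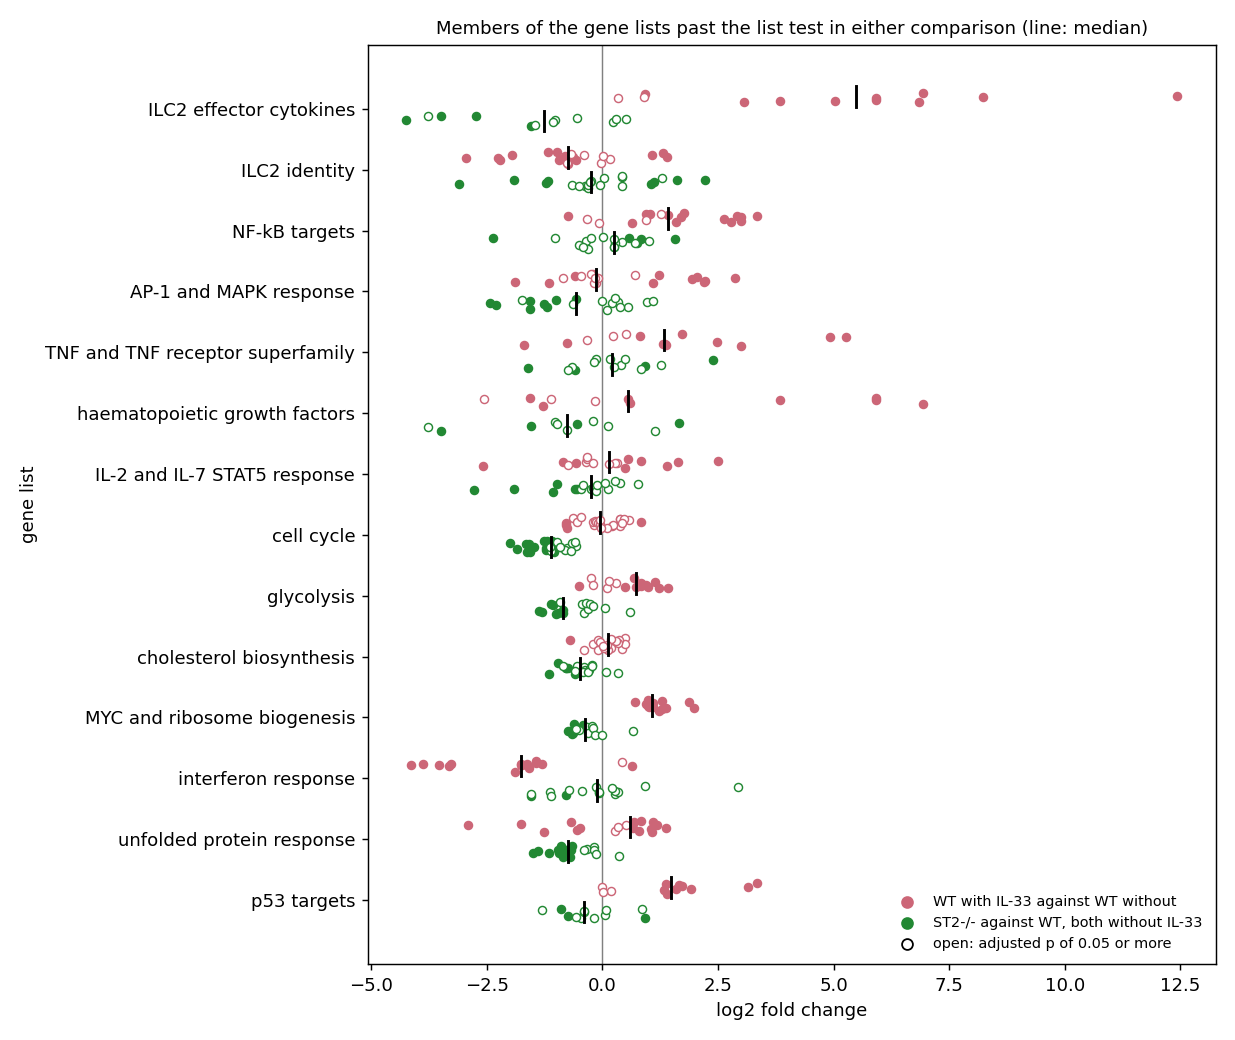
Log2 fold changes of the members of each gene list past the list test in either comparison, with a point per gene and a line at each list's median. Medians of the effector cytokine list lie at 5.48 for IL-33 and at -1.26 for ST2 loss, and those of the cell cycle list at -0.04 and -1.10.

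ST2-/- cells without IL-33 and WT cells with IL-33 differ in genotype and cytokine together. Here 4058 genes were higher in ST2-/- and 3948 lower (8006 of 14423). The interferon list was higher and 13 lists were lower in ST2-/-, and of these 14 calls the effector cytokines alone held with an estimated correlation (adjusted p = 0.0307). Effector cytokine genes were lower in 10 of 12, MYC and ribosome biogenesis genes in 16 of 16, NF-kB targets in 16 of 19 and glycolysis genes in 13 of 17, the same counts as when adjusted over the list alone, and interferon genes were higher in 10 of 16. For the other 13 lists, adjusted p with an estimated correlation ran from 0.135 (unfolded protein response) to 0.662 (cell cycle), with 0.141 for the MYC list, 0.207 for NF-kB targets and 0.282 for both glycolysis and interferon genes. Library size scaling gave 7957 genes up and 1878 down, and a term for Y-linked transcripts gave 2351 up.

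Many of the same genes moved in opposite directions with added IL-33 in WT and in ST2-/- without it. Of the 1450 genes that fell in ST2-/-, 809 rose with IL-33 (282 for independent lists), and of the 728 that rose, 353 fell with IL-33 (120.2). Genes that went the same way were fewer than for independent lists, 54 up in both (141.6) and 140 down in both (239.5). Simulated unchanged groups against the same controls gave 0 calls in either comparison in 12 draws, and so 0 shared calls, which sets no level for these overlaps. Among genes with a mean CPM of at least 10, the 751 that rose at least 2-fold with IL-33 had a median log2 fold change of -0.55 in ST2-/-, and the 545 that fell had 0.21. Library size scaling gave -0.26 and 0.51, and the 0.21 became 0.07 without library 3 of WT or library 1 of ST2-/-. Across 14423 genes, which are not independent replicates, the correlation of the log2 fold changes was -0.296, and the covariance was -0.278 against 0.0247 in 40 simulated draws (difference -0.303). Those draws were centred on the observed controls and leave out the controls' own error, so they set no level for the sharing of controls. For the 7738 genes with a mean CPM of at least 10 the correlation was -0.355 (-0.423 to -0.285 over the alternatives), whereas over all genes its sign turned without library 3 of WT (0.291), with no filter (0.264) and with DESeq2 (0.196). The controls, at 3 libraries, cannot be split. Sharing them pushes fold changes the same way, so part of the overlap in the same direction may come from shared controls, while the opposite overlap and the negative correlation would be lowered by them.

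**Figure D3:**
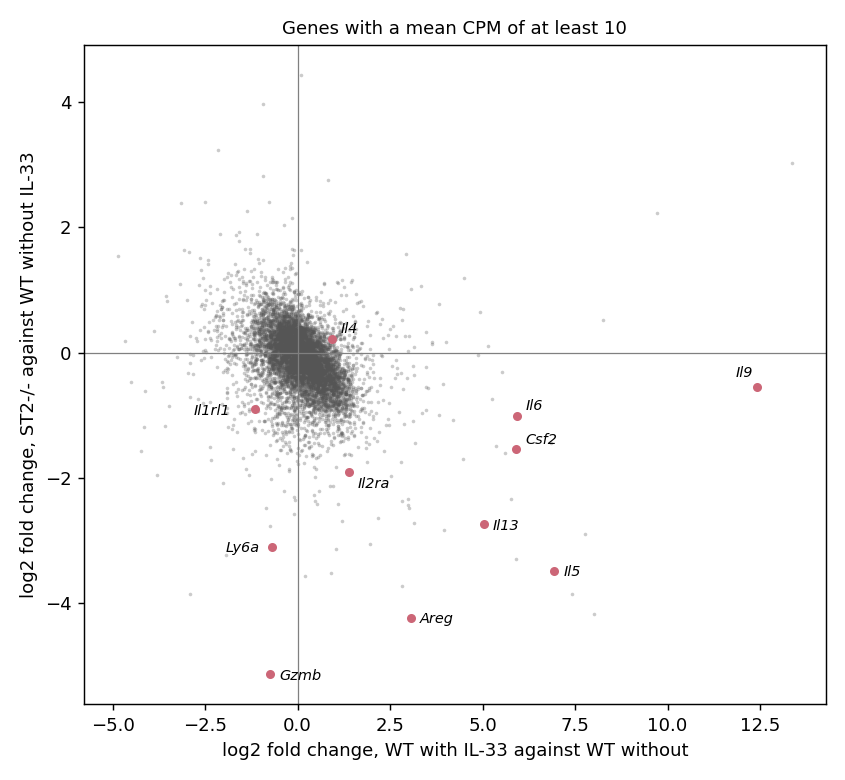
Log2 fold change with IL-33 in WT (x axis) against log2 fold change in ST2-/- without IL-33 (y axis) for the 7738 genes with a mean CPM of at least 10, a point per gene. The correlation across genes is -0.355, and Il5 (6.94, -3.48) and Areg (3.06, -4.24) lie at the lower right.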

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

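The tests of sex, of fewer ILC2s, of a lost IL-33 signal, of sequencing depth and of RNA from other cell types were chosen after the results were seen, and those of other splits, shared controls and silent genes before.

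In WT with IL-33, 4 of 60 measures tested had a library far from the other 3, where 3 are expected by chance. Serpinb1a stood at 29.1 CPM in library 3 against 13.1 to 15.4 CPM in the others. Klrg1 stood at 47.5 CPM in library 4 against 29.1 to 32.2 CPM. Tnfsf8 stood at 22.2 CPM in library 2 against 6.23 to 7.98 CPM, and Mdm2 at 281 CPM in the same library against 179 to 194 CPM.

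For the 5187 genes of the IL-33 comparison, 1 of the 35 splits of the 7 libraries gave as many, the real one (highest other 0). This is the smallest share these splits can give, which makes chance unlikely without excluding it. Other differences that follow the groups are not tested by the splits. The same held for the 8006 genes between ST2-/- and WT with IL-33, with 1 of 35 splits and a highest other of 0.

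The 2178 genes between ST2-/- and WT without IL-33 were weighed against a different cell mix and the sex of the mice. Strain, which the sample titles give for WT only, was not weighed. Fewer ILC2s in the ST2-/- sorts stays open, since the identity list's median of -0.24 (SD 1.21) lay 1.02 above that of the 12 effector cytokine genes (-1.26, SD 1.64), a gap within the spread. The 9 lists of other cell types had medians above 0 (0.10 to 1.20), but means under 0 for NK cells and ILC1 (-0.42), ILC3 (-0.21) and mast cells and basophils (-0.46). The lowest members of these were Gzmb (-5.14), Il22 (-4.18) and Prss34 (-3.98). Prss34 did not pass (adjusted p = 0.275 in edgeR) and ran from 0.087 to 57.1 CPM over the WT libraries without IL-33. None of the 8 tested passed with camera. With fry, progenitor markers (adjusted p = 0.00483, mean 0.84) and T cell markers (adjusted p = 0.0349, mean 0.54) passed. Sex cannot be told apart from genotype here, because only 1 ST2-/- library lacks Y-linked transcripts. Its fold changes had a median ratio of 0.62 (quartiles 0.399 and 0.872) to those of the other 2 over 2333 genes, 95.6% of them in the same direction. Those genes were called from the other 2 against the same WT libraries, which favours agreement, and no level without a genotype effect was set. A term for Y-linked transcripts left 82 calls, 81 of them among the 2178, while the median SE rose from 0.243 to 0.334. With 1 of 10 splits as large as the real one, the splits are too few for a share under 0.05, and the highest other split (595 genes) set ST2-/- library 1 with WT libraries 1 and 2, which follows the libraries' olfactory receptor reads.

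Opposite effects of IL-33 and of ST2 loss cannot come from the shared WT controls alone, since sharing them pushes the covariance above 0. The observed covariance was -0.278, and -0.170 for the 7738 genes with a mean CPM of at least 10. The correlation of those 7738 genes kept its sign in all settings, unlike that of all genes. Both covariances lay below all simulated values (0.0177 to 0.0316 and -0.0002 to 0.0028). Those draws were centred on the observed controls and leave out the controls' own error, so they set no level for the sharing. A candidate explanation is that WT cells without added IL-33 had received some IL-33 signal, in the marrow or in culture, that ST2-/- cells lacked. This hypothesis was drawn from the opposite effects and has no separate test here, so it is only described by the 55.8% of the genes that fell in ST2-/- and rose with IL-33, among them 8 of 8 glycolysis genes, 6 of 6 MYC list genes, 4 of 4 effector cytokine genes and 3 of 3 haematopoietic growth factors. Il5 and Csf2 are counted in both the cytokine and the growth factor lists, and Osm is also on the STAT5 list. Fallen genes of the AP-1 (4 of 8 rose, 2 fell), unfolded protein response (9 of 12 and 3) and STAT5 lists (4 of 6 and 1) split with IL-33, and most of the cell cycle and cholesterol genes did not pass (1 of 14 up and 1 of 6 down), with list medians of -0.14 (AP-1), -0.04 (cell cycle) and 0.11 (cholesterol). The cell cycle list had a median of -1.10 in ST2-/- (members -1.99 to -0.58) but no rise with IL-33 (members -0.79 to 0.83). That list as a whole thus showed no opposite effects. Its members, like those of the other lists named, went both ways with IL-33, so they decide nothing about a lost signal. Sex differs between the groups compared for ST2 loss, so the hypothesis stays open.

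More genes were detected in ST2-/- library 3 than in any other library. Sequencing depth is argued against, since at an equal 8941691 counts this library still had 16123 genes with at least 10 reads, against at most 13380 (SD 849) in the others. Genomic DNA or other reads from silent genes cannot be told apart from the rest, since it had reads in 677 of 1428 olfactory and vomeronasal receptor genes at that depth, and ST2-/- library 2 had 672 and library 3 of WT without IL-33 588, but with 934 CPM it held more such reads than any other. RNA of other cell types also stays open, since its marker sum was the highest of the 10 libraries for 2 of 9 lists, neutrophils and monocytes (893 CPM) and erythroid cells (35.1 CPM), although the bead depletion targeted Gr1 and Ter119. No biological explanation of this pattern was tested.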

How the results depend on the processing

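The term for Y-linked transcripts and the 2 settings that leave out several libraries were chosen after seeing the data. The Y-linked term takes up ST2-/- libraries 1 and 3, so its effect of ST2 loss is that of library 2 against WT. Of 1121 values of named genes under the alternatives, 1073 kept direction and side of the threshold, 38 lost and 6 gained a call, and 4 reversed. All 9 list calls for IL-33 held in 19 of 19 other settings of the model. Depth limits genes with few counts. The correlation over all genes changed sign in some settings, unlike that of genes with a mean CPM of at least 10, and the cause was not tested.

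Library size scaling gave 1366 up and 4864 down for IL-33, 2290 and 601 for ST2 loss and 7957 and 1878 for ST2-/- against WT with IL-33, since it drops the composition factor. For ST2 loss, genes up numbered 1112 with the stricter filter, which tests fewer genes, and 1102 with DESeq2, whose correlation of effects over all genes was 0.196. Only the 2 groups compared gave 359 up and 528 down for ST2 loss, with 40.6% of its calls kept, but 3090 up and 3130 down for IL-33. The IL-33 fit kept more libraries and had more calls from the start, so it cannot show whether fewer samples explain the drop. The ST2 loss calls given first rest on a spread shared with the WT libraries with IL-33. With the term for Y-linked transcripts, ST2 loss gave 38 up and 44 down, ST2-/- against WT with IL-33 gave 2351 up, and Il1rl1 had a log2 fold change of -0.81 and lost its call. Leaving out library 3 of both groups without IL-33 gave 240 up and 443 down for ST2 loss and a correlation of effects of -0.0174. Leaving out the 3 libraries with most olfactory receptor reads, which leaves 1 ST2-/- library assumed to vary like the others, gave 374 up and a correlation of -0.0455. With no filter, 17 lists passed for ST2 loss and the correlation was 0.264. An estimated correlation left 3 lists for IL-33 and 1 for ST2 loss, and fry called 14 for IL-33 and 11 for ST2 loss. Klrg1 in ST2 loss was 0.17 with the Y-linked term, and Il9 was 0.20 without library 3 of both groups and 0.40 without the 3 libraries. Where no reason is given, the cause was not tested.

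Leaving out 1 library at a time, IL-33 genes down ranged from 1470 to 2610, ST2 loss genes up from 201 to 868 and down from 680 to 1908, the correlation from -0.313 to 0.291, and Il9 in ST2 loss from -1.05 to 0.67. Of 9 same-number pairs, 2 had a correlation of deviations over 0.1 (median -0.102). Both set WT without IL-33 against ST2-/-, at 0.447 for libraries 1 and 0.5 for libraries 3, above the highest pair of unlike number (0.397). Libraries 2 of these groups stood at -0.207. Whether the replicate numbers pair the samples of the ST2 comparison is therefore left open. With the replicate block, 2432 genes were up and 1982 down for IL-33 and 515 and 1086 for ST2 loss.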

Other observations

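All observations here are values with no test of an explanation, and the genes of each list were named after their values were seen where they fall outside the 4 with the smallest adjusted p. A value alone in parentheses after a list is its camera adjusted p, and after a gene its log2 fold change.

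Gene lists that did not pass in WT ILC2s with IL-33 still held single genes that did. Among 12 checkpoint and inhibitory receptor genes, 5 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.627). Tigit rose to 10.0 ± 0.842 from 0.382 ± 0.16 CPM and Pdcd1lg2, the PD-1 ligand PD-L2, to 89.9 ± 15.9 from 15.5 ± 2.53 CPM, while Cd200r1 was 2.85-fold and Nt5e, the ectoenzyme CD73, 8.40-fold lower. Among 12 chemokine genes, Cxcl2, Cxcl3, Cxcl1 and Ccl3 rose and none fell (7 up adjusted over the list alone; camera adjusted p = 0.0618), with Cxcl3 at 899 ± 204 against 58.1 ± 33.6 CPM. Of 13 IL-33 receptor signalling genes, Irak3, Map3k7 and Il1rap rose and Irak2, Irak4 and Irak1 fell, also when adjusted over the list alone (camera adjusted p = 0.864; median -0.03, mean 0.09). Irak3, an inhibitory member of its kinase family, was 7.48-fold higher. Unfolded protein response genes split, with 9 of 18 up, such as Creld2 (1.19), Manf (1.37) and Hspa5 (1.05), and 6 down, such as Trib3 (-2.90; 10 and 6 adjusted over the list alone; camera adjusted p = 0.161). In the AP-1 and MAPK list 7 of 19 rose, with Batf at 2.04 and Ier3 at 2.19, and Fos (-1.88), Dusp6 and Dusp5 fell, also when adjusted over the list alone (camera adjusted p = 0.145; median -0.14 but mean 0.44).

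The STAT5 response changed in both directions with IL-33 (6 up and 3 down of 17, the same adjusted over the list alone; camera adjusted p = 0.462), from Bcl2l1 at 2.51 to Bcl2 at -2.57. Lists with few or no changes were cholesterol biosynthesis (Nsdhl down of 18; 0.773) and mitochondrially encoded transcripts (0 of 15; 0.732). In the cell cycle list Ccnb1 was up and Mcm6, Mcm7 and Mcm2 were down of 25 (0 and 2 adjusted over the list alone; 0.773). Near Il1rl1, Il1r2 rose 11.4-fold and Il18r1 and Il18rap fell, of 8 neighbours tested (0.773; median -0.09, mean 0.29). Markers of other cell types that passed were Trbc1, Cd3g and Trbc2 down of 6 T cell genes (0.156), Ifng up of 7 NK cell and ILC1 genes (0 adjusted over the list alone; 0.732), Il22 and Il17f up and Rorc and Ltb4r1 down of 6 ILC3 genes (0.846), and Ighm down of 7 B cell genes (0.732). Cd48 fell among 7 progenitor genes (0.732; median -0.39, mean 0.04) and Pecam1 rose among 3 stromal and endothelial genes (0.509; median -1.48 though tested as up). Neutrophil and monocyte genes (0 of 11; 0.522) and mast cell and basophil genes (0 of 5; 0.773) did not pass. For the erythroid list (Hbb-bt up and Hba-a1 down, with shared reads between globin copies) and the sex-linked list (Xist alone, not past), too few genes were tested for a list test.

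ST2-/- ILC2s differed from WT in genes used to define the cells. Of 21 identity genes, Il17rb (3.06-fold, 196 ± 36.5 against 64.0 ± 15.5 CPM), Tcf7 (4.65-fold, 21.7 ± 8.85 against 4.64 ± 1.17 CPM), Gfi1 (2.17-fold) and Tox (2.06-fold) rose and Il2ra, Ly6a, Icos (-1.18) and Nmur1 (-1.21) fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.367). Tcf7, Gfi1 and Tox encode transcription factors of early ILC development. Kit, whose protein was gated against, was 4.09-fold higher (48.3 ± 24.7 against 11.8 ± 2.02 CPM, adjusted p = 0.00153 in edgeR), alone among 7 progenitor genes (camera adjusted p = 0.102). NF-kB targets Nfkb2 (0.74), Tnip1 (0.83), Tnfaip3 (1.57) and Relb rose and Bcl3 (-2.36) fell of 19 (5 and 2 adjusted over the list alone; camera adjusted p = 0.362). Ltb and Lta rose and Tnfsf4 and Tnfrsf1b fell of 14 TNF family genes (0.367), Nt5e and Cd96 rose and Cd200r1 and Havcr2 fell of 12 checkpoint genes (3 and 2 adjusted over the list alone; 0.695), and Cxcl3 fell of 12 chemokine genes (0.0939). Bbc3 rose and Tnfrsf10b and Zmat3 fell of 12 p53 targets (2 and 4 adjusted over the list alone; 0.285), Zbp1 and Bst2 fell of 16 interferon genes (0.323), and Myd88 fell by 0.39 of 13 receptor signalling genes (0.266). Il18r1 rose and Il18rap fell of 8 Il1rl1 neighbours (0.577).

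Markers of other cell types in ST2-/- passed for Trbc1 (up, of 6 T cell genes; list 0.194), Gzmb (down, of 7 NK cell and ILC1 genes; 0.655; median 0.74 but mean -0.42) and Il22 and Ltb4r1 (down, of 6 ILC3 genes; 0.367; median 0.76 but mean -0.21). None passed among B cell (7; 0.367), neutrophil and monocyte (11; 0.252), mast cell and basophil (5; 0.695; median 0.10 but mean -0.46), stromal and endothelial (3; 0.367) or mitochondrially encoded genes (15; 0.22). Erythroid genes (2 tested) and Xist did not pass and had no list test. Unless another count is given, counts over these lists were the same when adjusted over the list alone. Gzmb and Il22 also stood at 82.3 and 3.06 CPM in WT ILC2s without IL-33.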
